A study of Bos taurus with 6 samples.

How the data were processed

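RNA of bovine blastocysts made in vitro at 2 laboratories, called site A and site B, was compared directly on 6 two-colour Agilent arrays. Per the labels' protocols, total RNA was isolated with a kit for very small samples, amplified linearly, and coupled to Cy3 or Cy5 with a platinum-based labelling chemistry that attaches dye to the RNA itself. Each array held RNA of both sites. On 3 arrays site A was in Cy5 and site B in Cy3, and on the other 3 the dyes were swapped, with replicate numbers 1 to 3 in each orientation. The labels count 3 biological replicates per site. They do not say which arrays of the 2 orientations hold the same extracts, nor what a replicate was (a culture, a collection day or a pool). If those were not separate cultures, p-values measure only the spread between these samples.

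The deposited scanner files hold a mean intensity and a median local background intensity per spot and channel, written by Agilent Feature Extraction 10.7.3.1 with protocol GE2_107_Sep09, per the file headers. They also hold processed intensities that the scanner software had background-subtracted, detrended and dye-normalized, and flags per spot. A log10 ratio of processed red over green per spot was deposited with them, per the file headers, and entered no test. The deposited value table of the whole series holds log2 ratios whose scale, centring and direction the labels do not state. When set against log2 ratios with the local background subtracted and loess applied, all 6 columns gave a slope between 0.999 and 1.00 and r between 0.997 and 1.00. All 6 run as site A over site B. The columns' medians were -0.000903, -0.00222 and 0.00442 for site A in Cy5 and -0.00453, -0.00269 and -0.00509 for site B in Cy5. The submitters' exact steps are not given in the sources used here.

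Intensities were read with limma 3.58.1 in R 4.3.3. Background was corrected with normexp (offset 50), fitted on all spots. Log2 ratios were normalized within each array by loess with control spots at weight 0, and control spots and spots with an outlier flag were then left out. Ratios of arrays with site B in Cy5 had their sign turned, so that every value is site A over site B. Probes were tested when well above background on at least 4 of 6 arrays in the channel of at least 1 site, which 18435 of 43795 non-control probes were. Averages by replicate number needed both arrays, so outlier flags left no average for 49 of these, which were not tested, and a single average for 125. The latter were tested on the prior variance alone, and 60 of them passed. The 2 arrays with the same replicate number were averaged, and the 3 averages were fitted with 1 coefficient (lmFit, eBayes), with a two-sided test and Benjamini-Hochberg adjusted p under 0.05. This design, the filter, the rule for named items and most alternatives were fixed before the data were examined. The number of arrays limits the precision.

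Averaging by number treats same-numbered arrays as a technical swap of the same extracts, so this was checked. The deviations of each array from the mean of its orientation were correlated over the tested probes. Same-numbered arrays gave -0.44, -0.36 and -0.42, so the numbers were not taken to pair the arrays, which required every such correlation to be over 0.1. The pairs that deviated together were site A in Cy5 replicate 1 with site B in Cy5 replicate 2 (0.70), replicate 2 with replicate 3 (0.65) and replicate 3 with replicate 1 (0.69). A second fit averaged these partner pairs instead, numbered by the replicate with site A in Cy5. It was added after seeing the data. All 6 ways to match the arrays were computed in the same exploratory step in which the correlations were seen, after the count with the replicate numbers was known, and the partner pairs were taken from the correlations.

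The effect of a wrong match was tested on simulated data for 18435 probes, with spreads and dye effects taken from the arrays and extracts shared by the partner pairs. Averaging by replicate number then gave an unadjusted p under 0.05 for 16.9% of probes with no site effect, and averaging by partner pairs for 5.28%. At the adjusted threshold, with no changed probes, both gave 0 calls, so a wrong match alone made no calls there. With 200 changed probes, averaging by number made 423 calls, of which 241 were false. Averaging by partner pairs made 124 calls with 2 false, and recovered 0% of changes of 0.5 on the log2 scale, 54% of changes of 1, 96% of changes of 2 and 94% of changes of 3. Where the numbers were simulated as the true partners, averaging by number made 123 calls with 1 false and recovered 2%, 58%, 94% and 90% at these sizes. Averaging by partner pairs then made 414 calls, of which 231 were false. On the arrays themselves, 7622 of 18386 probes had an unadjusted limma p under 0.05 with the numbers, and how many truly changed is not known. The simulated cases of 0 and 200 changed probes therefore do not say how many real calls a wrong match made.

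The files give each probe a name and, in part of the files, its 60-base sequence, but no gene, and place it on no chromosome. The gene table used here (assembly ARS-UCD2.0) holds neither these names nor sequences. No probe was therefore given a gene, and the gene-level counts, gene lists and cell type markers planned beforehand were not run. The rule for named genes (adjusted p under 0.05, same sign in all 3 replicates, then the highest and lowest log2 ratios) was applied to probes, and only the first 2 in each direction are named. Probes were also joined into families when they shared 20 consecutive bases, or differed at 10 or fewer positions in register. Family means over the probes with all 3 averages were fitted in the same way. Families were defined after seeing the data.

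Alternatives covered the background correction, the normalization, the filter on dim probes, the use of the arrays (6 separate arrays with a dye term, with the replicate number, slide or partner pair as a block), each slide alone, the variance prior, the threshold, the deposited value table, each replicate left out, and an adjustment for base counts. The slide blocks and replicate blocks used duplicateCorrelation (statmod 1.5.0).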

Results

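The series asked whether blastocysts made with a shared protocol differ in their transcripts between laboratories. Blastocysts of 2 sites were compared on 6 arrays, 3 with site A in Cy5 and 3 with site B in Cy5. Per the labels, both sites shared the protocol, extract and semen. Oocytes came from slaughterhouse ovaries, from follicles of 2 to 6 mm, with at least 5 layers of cumulus cells. Site B embryos were recorded with International Embryo Technology Society stage code 7, the expanded blastocyst, and quality code 1. Site A embryos were not scored, so a difference in stage or quality cannot be told apart from site.

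The arrays differed in how much signal stood above background. In the arrays with site A in Cy5, 17104, 14843 and 18145 probes were well above background in the site A channel for replicates 1, 2 and 3, and 21450, 13806 and 22621 in the site B channel. With site B in Cy5, the site A channel had 25223, 27413 and 24256 such probes and the site B channel 17428, 18756 and 17447. Replicates 1 and 2 with site A in Cy5 lay on 1 slide and the other 4 arrays on a second slide, with the scan dates divided in the same way. The dye effect had an SD of 0.37 over probes on the log2 scale, against 0.29 for the mean site ratio. After turning the sign of swapped arrays, log2 ratios over the tested probes correlated at 0.54 to 0.74 between arrays of 1 orientation and at -0.25 to 0.09 between arrays of opposite orientation. Probes are not independent replicates.

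The highest ratios of site A over site B belonged to 2 probes of nearly the same sequence, which differ at 4 of 60 positions, so that binding to the same transcripts was not excluded. EMBV3_38346, with the sequence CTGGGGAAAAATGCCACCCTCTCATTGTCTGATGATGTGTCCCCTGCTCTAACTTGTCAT, had a log2 ratio of 2.31 ± 0.21 (SD, n = 3; limma adjusted p = 1.71e-05), or 4.95-fold. EMBV3_05852, with the sequence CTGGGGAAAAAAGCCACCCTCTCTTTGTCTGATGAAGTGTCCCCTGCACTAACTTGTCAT, had a log2 ratio of 2.25 ± 0.21 (SD, n = 3; limma adjusted p = 1.71e-05), or 4.76-fold. Both were higher at site A on 6 of 6 arrays. Averaging partner pairs uses the same 6 arrays and so leaves these ratios as they are. The SDs were then 0.57 and 0.46, and both probes kept a limma adjusted p of 0.037.

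The lowest ratios belonged to EMBV3_31163 and EMBV3_17294. EMBV3_31163, with the sequence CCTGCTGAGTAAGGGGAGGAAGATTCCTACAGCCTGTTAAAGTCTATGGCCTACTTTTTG, had a log2 ratio of -2.15 ± 0.50 (SD, n = 3; limma adjusted p = 0.000123), or 4.43-fold higher at site B. EMBV3_17294, with the sequence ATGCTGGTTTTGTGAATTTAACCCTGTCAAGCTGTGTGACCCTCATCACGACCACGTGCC, had a log2 ratio of -1.99 ± 0.42 (SD, n = 3; limma adjusted p = 0.00011), or 3.96-fold higher at site B. Both were lower at site A on 6 of 6 arrays. With partner pairs averaged, their SDs were 0.95 and 0.90 and they missed the threshold, with limma adjusted p of 0.054 and 0.0568. Within the slide of 4 arrays the limma adjusted p were 0.0585 and 0.0642. With median centring in place of loess, all 4 named probes kept their direction and missed the threshold, with limma adjusted p from 0.129 to 0.159. With partner pair 2 left out, all 4 also missed it. The genomic positions of these 4 probes are not given in the sources used here.

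**Figure D1:**
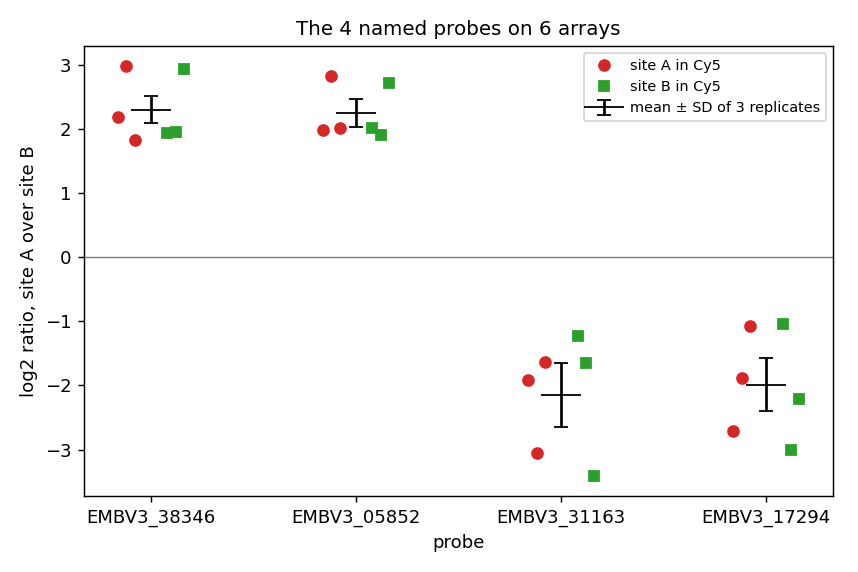
Log2 ratio of site A over site B (vertical axis) for the 4 named probes (horizontal axis), with 1 point per array, coloured by dye orientation, and a bar for the mean and SD of the 3 averages of same-numbered arrays. EMBV3_38346 and EMBV3_05852 lie above 0 and EMBV3_31163 and EMBV3_17294 below 0 on all 6 arrays.

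Over all tested probes, 5399 of 18386 differed between the sites when same-numbered arrays were averaged (limma adjusted p under 0.05), 3021 higher at site A and 2378 higher at site B. Loess sets the zero by the bulk of non-control probes on each array, so directions and sizes are relative to that bulk. On this scale the 10 spike-in transcripts had a mean log2 ratio of -0.39, and the median absolute log2 ratio of the 5399 was 0.39. Directions set against the spike-in transcripts could therefore differ. Same-numbered arrays deviated in opposite directions, which narrows the spread between their averages and so lowers these p-values. The p-values are too small if the partner pairs share extracts, which the labels do not say. With partner pairs averaged, 108 of 18416 tested probes passed, 67 higher at site A and 41 higher at site B. All 108 were among the 5399. In that fit 3677 probes had an unadjusted limma p under 0.05, and the lowest limma adjusted p was 0.0146. A limma adjusted p under 0.1 held for 999 probes and one under 0.01 for 0, so this count depends strongly on the threshold. Both fits average the same 6 arrays, so log2 ratios can differ between them only at probes with an outlier flag. Their correlation of 0.995 over probes is therefore no separate evidence. The median SD was 0.12 with the numbers and 0.20 with the partner pairs. The median change among the 5399 probes was 1.31-fold and among the 108 it was 2.03-fold, and 5.41% of tested probes differed by at least 1.5-fold. Sizes depended on the processing: of the 5399 probes, 991 reached 1.5-fold and 142 reached 2-fold. With the scanner's processed signals 4331 probes passed, of which 2746 reached 1.5-fold and 840 reached 2-fold. Of the 4331, 3270 were among the 5399. With no filter on dim probes, 4121 of 43746 tested probes passed. A strict filter, well above background in both channels of all 6 arrays, gave 4472 of 11468. Of these 4472, 2279 were higher at site A and 2193 higher at site B. The share higher at site A was 51.0% there, against 56.0% of the 5399 and 55.7% with no filter. All but 1 of the 108 probes had the same sign on all 6 arrays, as did 2495 of the 5399. Over all 18435 probes past the filter, 3041 (16.5%) did. Without replicate 2, 3533 probes passed, and partner pairs 1, 2 or 3 left out in turn gave 7, 0 and 1653, with 2189 at an unadjusted limma p under 0.05 where the count was 0. Median centring in place of loess gave 0 in limma, with 3085 at an unadjusted p under 0.05. The 6 arrays as separate samples with a dye term gave 2711. With the slide as a random block, 1704 probes passed, and 557 passed within the slide of 4 arrays, of which 35.2% were higher at site A. In the slide of 2 arrays, where dye and site are not separable, 2695 passed, of which 69.1% were higher at site A.

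**Figure D2:**
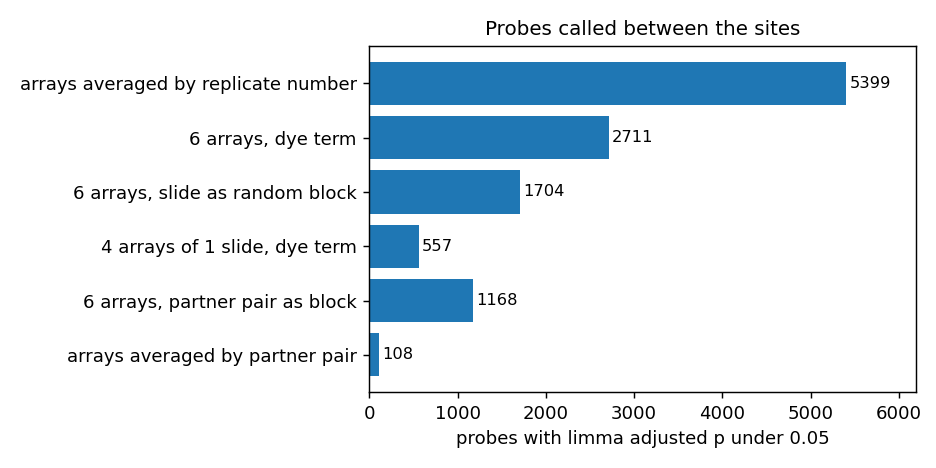
Number of probes with a limma adjusted p under 0.05 (horizontal axis) under 6 treatments of the same arrays (vertical axis). The count is 5399 with arrays averaged by replicate number and 108 with arrays averaged by partner pair.

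**Figure D3:**
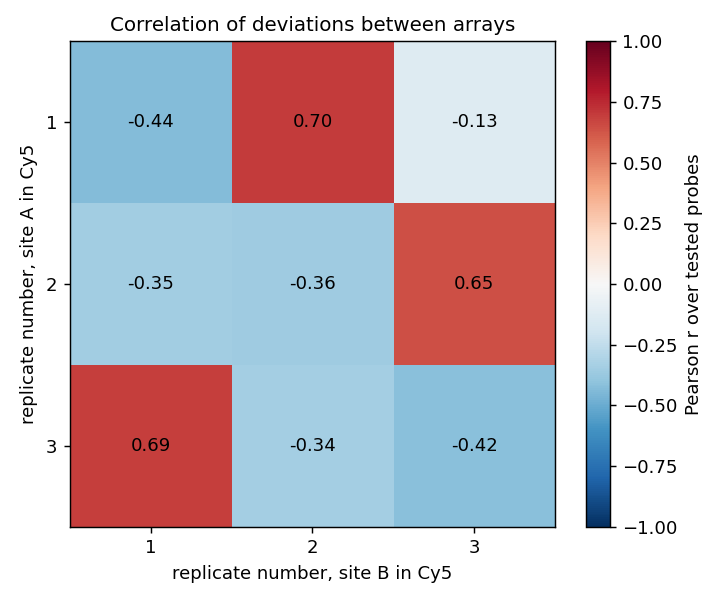
Pearson correlation, over the tested probes, of array deviations from the mean of their dye orientation, for each array with site A in Cy5 (rows) against each with site B in Cy5 (columns). The same-numbered arrays on the diagonal lie at -0.44, -0.36 and -0.42, and each row holds 1 positive value, 0.70, 0.65 and 0.69 from the top.

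Counts of probes overstate the number of transcripts, since many probes share sequence. The 17969 probes with all 3 averages formed 15900 families. Of these, 4396 passed when same-numbered arrays were averaged, 2522 higher at site A, and 43 passed with partner pairs averaged, 25 higher at site A. The family fit tests the mean of each family, so it also changes the value tested. The 5399 probes themselves, some of them with fewer than 3 averages, fell into 4723 families and the 108 into 89. Among 29 families with at least 8 tested probes, 17 passed with the numbers, 5 higher at site A and 12 higher at site B. Of these 12, 11 were families of 18 probes with 10 copies of 1 sequence, whose target the files do not give; among the other families, 5 were higher at site A and 1 at site B. With partner pairs, 0 of the 29 passed in limma, with 16 at an unadjusted p under 0.05. Of these 29 families, the one with the largest change had 15 probes, all above 0 with the numbers, with a family log2 ratio of 0.84 ± 0.01 (SD, n = 3; limma adjusted p = 0.000257), or 1.79-fold. Its SD was 0.12 and its limma adjusted p 0.0527 with partner pairs, although 10 of its 15 probes passed singly. A second family of 8 probes had a log2 ratio of 0.80 ± 0.10 (SD, n = 3; limma adjusted p = 0.00037), and 0.0677 was its limma adjusted p with partner pairs.

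A few probes were well above background at 1 site only. On all 6 arrays, 12 probes were well above background in the site A channel and not in the site B channel on any array, and 0 probes were the reverse. With at least 5 of 6 arrays required, the counts were 45 at site A and 1 at site B. Detection was uneven, with up to 27413 probes well above background on an array for site A and up to 22621 for site B. These counts cannot tell such uneven detection apart from a difference between the sites. The lower bounds of the folds of the 12 probes, taken per channel after loess and Aquantile against the lowest signal well above background, ran from at least 1.06-fold to at least 2.15-fold. Of the 12, 11 passed in limma with the replicate numbers and 0 with partner pairs, where 9 had an unadjusted p under 0.05. The 12 were picked for higher signal at site A on these same arrays, so these tests are no separate evidence.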

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

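The tests of extract sharing and slide for the first pattern, the spike-in test and all counts over sign assignments were chosen after the values were seen.

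The site ratio of 3107 probes differed between the dye orientations (dye term over 6 arrays, limma adjusted p under 0.05). The 10 spike-in transcripts, which the comparisons leave out, had a mean log2 ratio of site A over site B of -0.39 ± 0.08 (SD, n = 3) with the replicate numbers. All 10 had a log2 ratio below 0, from -0.62 to -0.19. The SD of their mean was 0.14 with partner pairs, and single arrays ran from -0.83 to 0.14. No control level fits this signal, since negative control probes lie near background on any RNA.

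Arrays of opposite dye orientation deviated together by other numbers than their own. A candidate explanation is that the numbers of both orientations do not mark the same extracts, since the lowest of the 3 partner correlations was 0.65. Centring within each orientation makes the other correlations negative once these are high, so the same-number values are no separate evidence. With 3 arrays per orientation and probes that vary together, the level chance gives is not known, and this stays a hypothesis from the same values. The tables argue against a trend with base composition and brightness, because the lowest correlation was 0.68 after each array was adjusted for both. A shared slide does not account for it either, since a partner pair on different slides correlated at 0.70. No biological explanation was tested, because the labels give no grouping within the sites.

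The sign of the 3 averages can be assigned in only 4 distinct ways, too few for a share under 0.05. The real assignment was the only 1 to give as many probes, 5399 with the replicate numbers and 108 with partner pairs, and the highest of the others was 0 in both. The 3 averages correlated at 0.68 to 0.77 with the numbers and at 0.33 to 0.57 with partner pairs. Turning the sign of 1 average sets it against the others, so low counts were likely from the start. This holds whatever the averages share, so the counts are no separate evidence of a site effect.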

How the results depend on the processing

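Every setting with partner pairs, other matches of the arrays, base counts or at least 2 averages was added after seeing the data. The gene-level, gene list and cell type results were not run under any setting, because the probes have no gene. The count of 5399 stayed within 1.5 times under no background subtraction, processed signals, both filters, trend and robust priors, deposited values and base counts. All keep the replicate numbers. Aquantile leaves the log ratios as they are and so tests nothing here. Leaving out 1 replicate gave 3533 (without replicate 2) to 4880 (without replicate 3). Median centring gave 0 in limma, with 3085 at an unadjusted p under 0.05; the median SD was 0.26 with it against 0.12 with loess. Processed signals gave larger changes, and 3270 of their 4331 calls were among the 5399. Requiring 1.5-fold gave 991, or 993 with unadjusted p. The replicate block gave 5511 and 6 arrays with no replicate block 2711. The numbers were not taken as a pairing: no array with site A in Cy5 correlated best with its own number, and the block correlation was -0.39. The slide as random block gave 1704, the slide of 4 arrays alone 557 and the slide of 2 arrays alone 2695. Requiring at least 2 averages per probe gave 5336. Partner pairs gave 108, also with at least 2 averages, and without pair 1, 2 or 3 they gave 7, 0 (2189 at an unadjusted p under 0.05) and 1653. Partner pairs with trend and robust priors gave 639, as a block over 6 arrays 1168, after adjusting for base counts 244, and 151 in the deposited values. Of the other 4 matches of the arrays, 3 gave 2811, 3045 and 1258, and the fourth, 3924, was within 1.5 times. The numbers as labelled gave the most calls of all 6 matches and the partner pairs the fewest. Partners were picked for the highest correlations of deviations, which widens the spread between averages. Same-numbered arrays deviated in opposite directions, which narrows it. This ranking is therefore no separate evidence for either match. For the changes under the other settings the cause was not tested. The 4 named probes kept their sign in all 31 settings, which is little evidence. Many settings leave their log2 ratios as they are. The probes were also picked for extreme ratios of the same sign in all 3 replicates, so leaving out a replicate could not reverse them. The 2 higher at site A missed the threshold in 2 settings each, and EMBV3_31163 and EMBV3_17294 in 6 and 7. Signal over background limits the tests to 18435 of 43795 probes.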

Other observations

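The matches on brightness and number of C and the tests within brightness bins and within replicate 3 were set before their results were seen. The other tests in this part, with the probe families themselves and the adjustments for base counts, were chosen after values were seen.

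The array holds 12 families of 18 probes, each with 10 copies of 1 sequence and further probes that overlap it. All 12 had a mean log2 ratio below 0, from -0.54 to -0.04 with a median of -0.40, and 11 passed in limma with the replicate numbers, while 0 passed with partner pairs, where 11 had an unadjusted p under 0.05. The tables argue against brightness and base composition as the whole cause, because single probes matched on brightness and number of C had a median log2 ratio of -0.017. With each array adjusted for all base counts and brightness, all 12 family means stayed below 0, with a median of -0.36. The mean of the spike-in transcripts, -0.39, lies inside the range of these families, so a candidate explanation is that they measure transcripts added to the RNA. The files do not say what they measure, and a difference between the embryos of the sites stays open and untested.

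The site ratio rose with the number of C in the probe (Spearman's rho 0.26 over probes, which are not independent) and fell with the number of G (-0.19). The tables argue against probe brightness as the cause, since the median rho within 10 brightness bins was 0.25. Dye bias left where swapped arrays lie on different slides stays open: in replicate 3, whose arrays share a slide, the rho was 0.14, between the values that would have decided it. In the partner pair that shares a slide it was 0.03, a value looked at afterwards. That pair and replicate 3 share an array, so these values are not independent. The dye effect had a rho of 0.21 with the number of C. For the number of G, the rho was -0.22 and -0.25 in replicates 1 and 2, -0.036 in replicate 3 and 0.013 in that partner pair, and the dye effect had a rho of -0.39 with it. Adjusting each array for base counts gave 5213 probes with the replicate numbers and 244 with partner pairs.

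Among tested probes, 259 sequences were spotted under more than 1 probe name. The log2 ratios of their first 2 names correlated at 0.97 over sequences, with a median absolute difference of 0.06.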
